A study of Homo sapiens with 15 samples.

How the data were processed

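The authors deposited 1 table of values with 54675 probe sets for 15 arrays, and all 15 columns were used. Per the labels the RNA was total RNA, biotin-labelled and hybridised by the Affymetrix standard protocol, and the submitters' processing notes name GCRMA, which corrects background, normalizes and summarizes probes, without a version. As deposited, the log2 values had thus been background-corrected, normalized and summarized by GCRMA per the authors' notes. The values run from 0.173 to 14.46, and that they are on a log2 scale was inferred from them. Image processing settings and the chip description used were not given in the sources used here. No raw intensities were processed.

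Probe sets were matched to genes by the platform's annotation, and the gene symbols were checked by gene identifier, which changed 0 of them. Of all probe sets 41097 had 1 gene symbol, 1801 had several and 11777 had none, with the 62 Affymetrix controls counted among these. Each of 19775 genes was read from its probe set with the highest mean over the 15 arrays, a choice that applied to the 10523 genes with more than 1 probe set. For the fermentation arrays genes with a log2 value of at least 5 in at least 4 of 12 arrays were tested, which left 8737. For comparisons with a single array, genes with a log2 value of at least 6 on the brighter side were compared, and a gene was counted from a log2 difference of 1. A side with all of its arrays under log2 5 was set to the higher of 5 and its own value and the difference given as a bound, and genes were ranked only where all arrays compared were at 5 or more. These bounds and ranks were chosen after the data were seen. No pseudocount was needed and the deposited values were not normalized again.

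The models were fitted with limma 3.58.1 in R 4.3.3, with the concentration and the vessel as factors, so vessel was a block for each comparison of concentrations and 6 residual degrees of freedom were left (5 for the interaction). The median residual SD was 0.147 and limma's moderated degrees of freedom were 9.2. The trend along the vessels and the interaction of concentration and vessel used linear terms. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Arrays of a vessel resembled each other at different concentrations. With the concentration mean taken out, the correlation of 12 pairs of arrays from the same vessel had a median of 0.376, and 10 were above 0.1. Pairs from other vessels had a median of -0.114, but taking out the mean ties this value to the first, so it is no separate evidence. The pairs of vessel 1 had 0.421 to 0.781 and those of vessel 3 had 0.024 to 0.25. Only 4 arrays correlated best with an array of their own vessel.

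A total of 34 gene lists with 528 entries were written beforehand from general knowledge, of which 471 were matched to a gene. They hold 516 different genes, 12 of them in more than 1 list. For the fitted comparisons 29 lists were tested with camera (preset correlation, and again with an estimated correlation) and fry over the same genes. Camera compares a list with the other genes, while fry asks whether the list's genes move one way on balance. With a preset correlation camera passed 8 lists for 2% against 0%, 8 for 1% against 0%, 7 for 2% against 1%, 9 along the vessels and 8 for the interaction. With an estimated correlation it passed 0 in each, and fry passed 9, 9, 0, 1 and 0. For single arrays each list's median was placed among 10000 random lists of genes of like level (20 level bins, seed 1).

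Genes named in the report follow a rule: the 8 largest rises and falls among the genes that passed, with the same sign in all 4 vessels for concentrations, up to 4 members of each list with the smallest p (the largest difference for single arrays), and CDKN1A, CCND1, MYC, PCNA, PTGS2 and CPT1A in any case. Where none passed, genes with the smallest p were named as not passing. IL33 and CADPS were named outside the rule, after their values were seen. These rules, the lists, the models, the thresholds and the alternatives were set before the data were examined, and alternatives added later are called so where they appear.

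The alternatives changed 1 choice at a time, apart from a later fit that left out vessel 1 and the block together: no filter or a stricter filter for low signal, the mean of a gene's probe sets, every probe set on its own, quantile normalization of the deposited values again, centring on the array median, an intensity trend with a robust prior, array weights, no replicate block, only the 8 arrays compared, a minimum 1.5-fold change, other forms of the vessel term, NaCl as the control, a spread borrowed from the fermentation arrays for single arrays, and leaving out each array in turn. For each count and the correlation the other splits of the same arrays were also counted (all 35 for concentrations, 100 drawn orders of the vessels otherwise, and, added after the data were seen, the 8 splits that part all 4 vessel pairs and the 12 orders that keep the vessels matched over the concentrations). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

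The fits were tried on simulated values for 8737 genes with known changes of log2 0.5, 1 and 2. For 2% against 0% they found 73.1%, 92.5% and 97.0% of the changed genes, with 3.8% of calls false. For 1% against 0% they found 67.2%, 92.5% and 97.0% (3.4% false) and for 2% against 1% 73.1%, 91.0% and 98.5% (3.3% false). Along the vessels they found 100% at each size (4.8% false) and for the interaction 97.0%, 98.5% and 100% (9.2% false). These sizes were per vessel step, and for the interaction per 1% of polydextrose and vessel step. In the data the largest rise that passed along the vessels was 0.68 (ULBP1). The simulated vessel trend also held no other difference between vessels. These shares thus do not give the power for the smaller slopes of the data. Of 30 simulated lists 3 had been shifted by 0.5, and camera with the preset correlation passed these 3 and 0 others. The simulated genes varied independently, while the estimated correlation was 0.658 in the real mitosis list. The check therefore could not show false calls that come from correlated genes.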

Results

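Gene expression was measured in Caco-2 cells, an epithelial line from a human colon carcinoma, which were used before they had differentiated. The cells were treated for 24 h in serum-free medium in 15 different ways, and the total RNA from each was read on a single Affymetrix array. For 12 of the arrays cell-free fluid from a colon simulator was added at 10% by volume, in which polydextrose, a poorly digested glucose polymer, had been fermented for 48 h at 0%, 1% or 2%. The simulator has 4 connected vessels that stand for the ascending colon (vessel 1), the transverse colon (vessel 2), the descending colon (vessel 3) and the sigmoid colon and rectum (vessel 4), so each concentration had 4 arrays, 1 per vessel. The other 3 arrays were medium alone, 100 mM NaCl, a salt control, and 5 mM butyrate, a short-chain fatty acid that gut bacteria make from fibre and that inhibits histone deacetylases. The 4 fluids of a concentration came from 1 simulation and the labels list no repeat. The p-values below thus measure only the spread among these 12 arrays, and the number of arrays limits the precision. Any difference between the simulations cannot be told apart from the polydextrose concentration. What is called an effect of polydextrose below includes any such difference. After genes with low signal were left out, 8737 genes were compared between the fermentation arrays.

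The arrays were alike in signal, with 42.27% to 44.1% of genes at a log2 value of 5 or more. Where every array on one side of a difference lay under log2 5, the difference is given as a bound against that limit. The difference between the 3′ and 5′ control probe sets of ACTB, a sign of RNA integrity, was 0.951 in medium, 0.641 with NaCl and 0.585 with butyrate. At each concentration this difference was highest in vessel 1, at 0.726 with 0%, 0.924 with 1% and 0.620 with 2%, against 0.366 to 0.636 in vessels 2 to 4. Principal component 1 held 57.2% of the variance and ran from medium (-65.42) and NaCl (-65.34) to butyrate (35.74). On it vessels 2 to 4 lay between -2.16 and 0.96 with 0% fluid, between 17.54 and 18.63 with 1% and between 26.27 and 32.27 with 2%. The arrays of vessel 1 lay lower, at -19.75 with 0%, -17.79 with 1% and -6.19 with 2%. Component 2 held 18%.

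**Figure D1:**
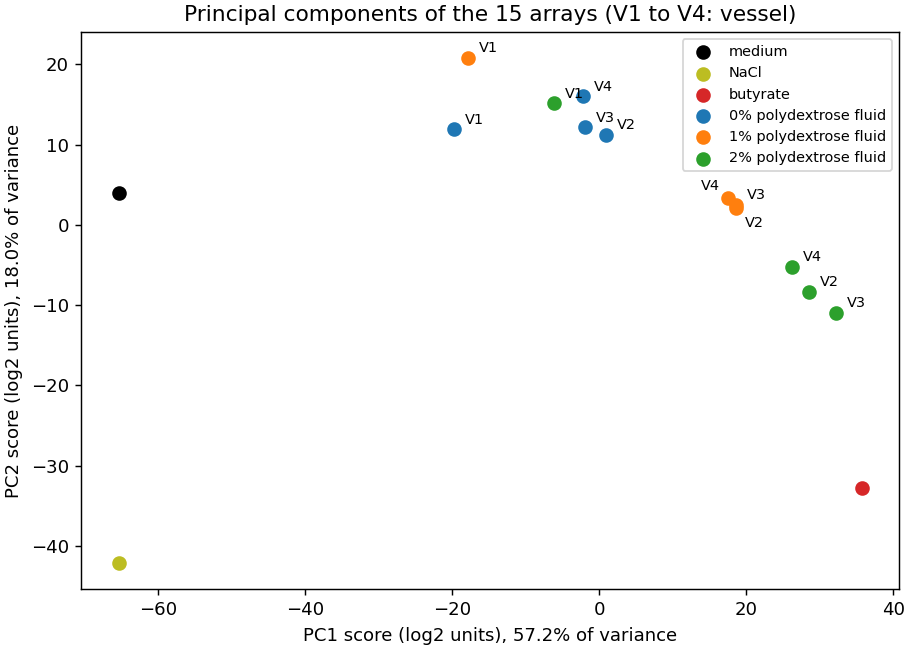
Principal components 1 and 2 (57.2% and 18% of the variance, log2 units) of the 15 arrays, 1 point per array, with colour for the treatment and the vessel number beside each fermentation array. Along component 1 the arrays of vessels 2 to 4 lie near 0 with 0% fluid and between 26.27 and 32.27 with 2%, while butyrate lies at 35.74 and the arrays of vessel 1 lie lower than the others of their concentration.

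The comparison of 2% with 0% polydextrose asks what fermenting the fibre added to the effect of the fluid itself, with 1 simulation each. Genes that drive cell division fell. All 24 measured genes of mitosis fell (median log2 change -1.06), among them UBE2C, which marks mitotic cyclins for destruction (-1.40), and the spindle proteins KIF11 (-1.13) and TPX2 (-0.98). PLK1, a kinase needed to enter mitosis, fell from 5.66 ± 0.46 to 4.04 ± 1.05 (SD, n = 4), with 3 of the 4 arrays of 2% under log2 5. The kinetochore motor CENPE was under it in all 4, a change of -0.41 or below, and with CENPE at that bound the median was -1.03. Of 27 DNA replication genes 18 fell, 0 rose and 9 did not pass (median -0.43, or -0.41 with 1 low gene at its bound), with TYMS, the thymidylate synthase, from 10.85 ± 0.47 to 9.86 ± 0.56 (SD, n = 4) and the helicase subunits MCM2 (-0.62) and MCM3 (-0.66) as examples. Of 12 genes of Wnt signalling and intestinal stem cells 5 fell (median -0.46), including the stem cell receptor LGR5 (-1.65), the stem cell transcription factor ASCL2 (-1.17), the surface protein CD44 (-0.71) and MYC, a transcription factor that promotes growth, from 10.88 ± 0.14 to 10.21 ± 0.46 (SD, n = 4).

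Histone and growth arrest genes rose in the same comparison. Of 9 histone genes 7 rose and 1 fell (median 0.60): H4C8 rose from 7.36 ± 1.15 to 9.23 ± 1.48 (SD, n = 4), H2BC21 by 1.42, H2BC4 by 1.24 (1 array of 0% under log2 5) and the linker histone H1-2 by 0.64. Of 12 growth arrest genes 7 rose and 1 fell (median 0.33, or 0.30 with 1 low gene at its bound). The cyclin-dependent kinase inhibitor CDKN1C rose by 1.41, the stress-induced GADD45B by 0.63 and CDKN1A, the kinase inhibitor induced by p53, from 10.22 ± 0.25 to 10.69 ± 0.40 (SD, n = 4). Of 10 genes known to respond to deacetylase inhibitors 6 rose (median 0.38), among them MAP1LC3B, an autophagy protein, by 0.58. CDKN1A stands in both of the last lists. Without vessel 3 of 0%, vessel 4 of 0%, vessel 2 of 2% or vessel 3 of 2%, CDKN1A no longer passed, with an adjusted p of up to 0.0546. At both concentrations the 3′ to 5′ difference of ACTB was highest in vessel 1. It was also higher with 0% than with 2% in each vessel. From vessel 1 to 4 it was 0.726, 0.596, 0.636 and 0.582 with 0%, and 0.620, 0.547, 0.547 and 0.551 with 2%. RNA quality was not in this model, so its part in the comparison was not tested.

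Among the genes that passed with the same sign in all 4 vessels and a log2 value of 5 or more in all 8 arrays, the largest rises were those of the immediate-early transcription factors EGR3 (2.09) and FOS (1.77) and of H4C8 (1.86). DNER, a transmembrane protein of the Notch pathway, was under log2 5 in all 4 arrays with 0% fluid (4.25 ± 0.53) and at 6.95 ± 1.67 with 2% (SD, n = 4), a rise of at least 1.95. DHRS2, a short-chain dehydrogenase, was under it too (4.01 ± 0.41 against 6.46 ± 1.66) and rose by at least 1.46. In vessel 1 both stayed under log2 5 with 2%, while in vessels 2 to 4 DNER was then at 7.42 to 8.06 and DHRS2 at 6.85 to 7.66. ZCCHC12, a zinc finger protein (2.40), and the Notch target HEY1 (1.65) also rose, from values under the limit in 3 arrays and 1 array of 0%. The largest falls among genes over the limit in all 8 arrays included ALDH3A1, an aldehyde dehydrogenase, from 9.04 ± 0.50 to 6.89 ± 1.44 (SD, n = 4), HMGA2, a chromatin protein of proliferating cells, from 8.02 ± 0.52 to 6.04 ± 1.42, BORA, an activator of mitotic kinases (-1.67), and SLC7A7, an amino acid transporter (-1.59). EPS8L3 fell as well (-1.71, with 2 arrays of 2% under log2 5). IL33, an alarmin of epithelial cells that was singled out after its values were seen, passed with -2.93 (adjusted p = 0.0233). It differed by 0.46 in vessel 1, while in vessels 2 to 4 it was at 7.77 to 8.44 with 0% and under log2 5 with 2% (3.23 to 4.65). Left out in turn, each of vessels 2 to 4 of 0% and of 2% took IL33 out of the genes that passed (adjusted p up to 0.0883).

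Genes of cell death moved in both directions. Of 14 pro-apoptotic genes 3 rose and 4 fell, with CASP9, an initiator caspase (0.69), and BIK (0.53) among the first and FAS, a death receptor (-0.55), among the second, and the list did not pass against other genes (adjusted p = 0.851). The oxygen-stress enzyme HMOX1 rose from 9.02 ± 0.58 to 10.16 ± 0.95 (SD, n = 4), while 3 of the other genes on its NRF2 list of 14 fell. Of 8 heat shock genes 3 fell, including the chaperones HSPH1 (-0.70) and HSPE1 (-0.59), and 1 rose. Of 15 genes of fatty acid oxidation and ketogenesis 3 rose, with ETFDH, an electron transfer enzyme, at 0.75. CPT1A, which brings fatty acids into mitochondria, was at 9.0 ± 0.13 with 0% fluid against 5.97 in medium and its difference of -0.03 did not pass (adjusted p = 0.890). PTGS2, the inducible cyclooxygenase, did not pass either (-1.40, from 6.97 ± 1.22 to 5.57 ± 0.98, SD, n = 4, adjusted p = 0.168): it differed by 1.67 in vessel 1 and by -2.03, -2.77 and -2.48 in vessels 2 to 4, where vessel 3 of 2% was under log2 5 (4.53). The same split of signs was seen in the chemokine CXCL3 (1.53 in vessel 1, -2.06 to -2.54 elsewhere) and in CXCL1 (0.67 and -0.98 to -1.26). In a fit without vessel 1, an alternative chosen after seeing the data, PTGS2 (-2.43), CXCL3 (-2.26) and CXCL1 (-1.13) passed with adjusted p of 0.00063, 0.000286 and 0.000453. Without vessel 1 of 0% alone they passed too, at 0.000271, 0.000134 and 0.000235, the lowest of all alternatives, of which the highest gave 0.405, 0.450 and 0.422. CCND1, a G1 cyclin (-0.12), and PCNA, the replication clamp (-0.24), did not pass.

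By limma with vessel as a block, 1820 of 8737 genes passed at an adjusted p under 0.05, of which 843 rose and 977 fell, and 1637 of them had the same sign in all 4 vessels. At least 2-fold changes were seen in 161 of these, 57 up and 104 down. By camera with a preset correlation 8 of 29 lists differed from the other genes, and with an estimated correlation 0 did. Mitosis (adjusted p = 1.14e-19) and DNA replication (1.1e-10) each had an adjusted p = 0.269 with an estimated correlation. Histone genes (1.3e-05), genes of the response to deacetylase inhibitors (0.000343) and growth arrest genes (0.00165) each had an adjusted p = 0.105 with an estimated correlation. Wnt and stem cell genes (0.000618) had an adjusted p = 0.575 with an estimated correlation. Metallothioneins, metal-binding proteins of which 2 of 6 rose (0.0138), had an adjusted p = 0.434 with an estimated correlation, and targets of the aryl hydrocarbon receptor, of which 3 of 6 fell (0.0435), an adjusted p = 0.553 with an estimated correlation. Without vessel 1 of 2% the metallothioneins no longer passed (0.0565), and without vessel 2 of 0%, vessel 1 of 1%, vessel 2 of 2% or vessel 4 of 2% neither did the receptor targets (up to 0.0773). With a higher limit for signal the targets were at 0.0731, and without all arrays of vessel 1 the metallothioneins were at 0.0505. Adjusted over the list alone, 24 mitosis, 21 DNA replication, 8 Wnt and 4 receptor target genes fell, 8 histone, 8 growth arrest, 7 inhibitor response and 4 metallothionein genes rose, and 1 histone and 1 growth arrest gene fell.

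With no block for vessel 0 genes passed by limma (1952 at an unadjusted p under 0.05, smallest adjusted p 0.214), while all 8 lists kept their camera call. With no block and without vessel 1, a fit chosen after seeing the data, 3352 genes passed, so the 0 depended on the arrays of vessel 1. With the block the count was 3205 without vessel 1, 863 from the 8 arrays of these concentrations alone, 3058 without vessel 1 of 0%, and 656, 703 and 909 without vessels 2, 3 and 4 of 0%. It was 767, 761 and 798 without vessels 2, 3 and 4 of 2%.

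Other lists held few genes that passed at 2%. Of 14 endoplasmic reticulum chaperones 4 fell and of 36 genes of oxidative phosphorylation 2 fell. In the TCA cycle 1 of 16 genes rose and 1 fell, and of 14 genes of the amino acid response driven by ATF4 2 rose. None of 20 glycolysis, 11 hypoxia, 7 hypertonic stress, 4 enterocyte or 16 ribosomal protein genes passed, counts that come from limma. A single gene rose among 17 of cholesterol synthesis, 8 of fatty acid synthesis, 8 of the prostaglandin pathway and 10 of NF-kB inflammation, and a single gene fell among 13 of tight junctions and 3 of goblet cells. Of 8 histone deacetylases 2 rose, and of 6 anti-apoptotic genes 1 rose and 3 fell. None of these lists differed from the other genes by camera. Median and mean differed in sign for the NF-kB (0.04 and -0.20), TCA cycle (0.05 and -0.02), histone deacetylase (-0.01 and 0.08), prostaglandin (0.02 and -0.07) and hypertonic stress lists (-0.02 and 0.01), and the pro-apoptotic list had a median of -0.02 while camera ranked it upward. Lists for fibroblasts, leukocytes, liver-type secreted proteins, bile acid receptors and short-chain fatty acid transport held too few measured genes to be tested. SLC16A1 was not analysed here.

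**Figure D2:**
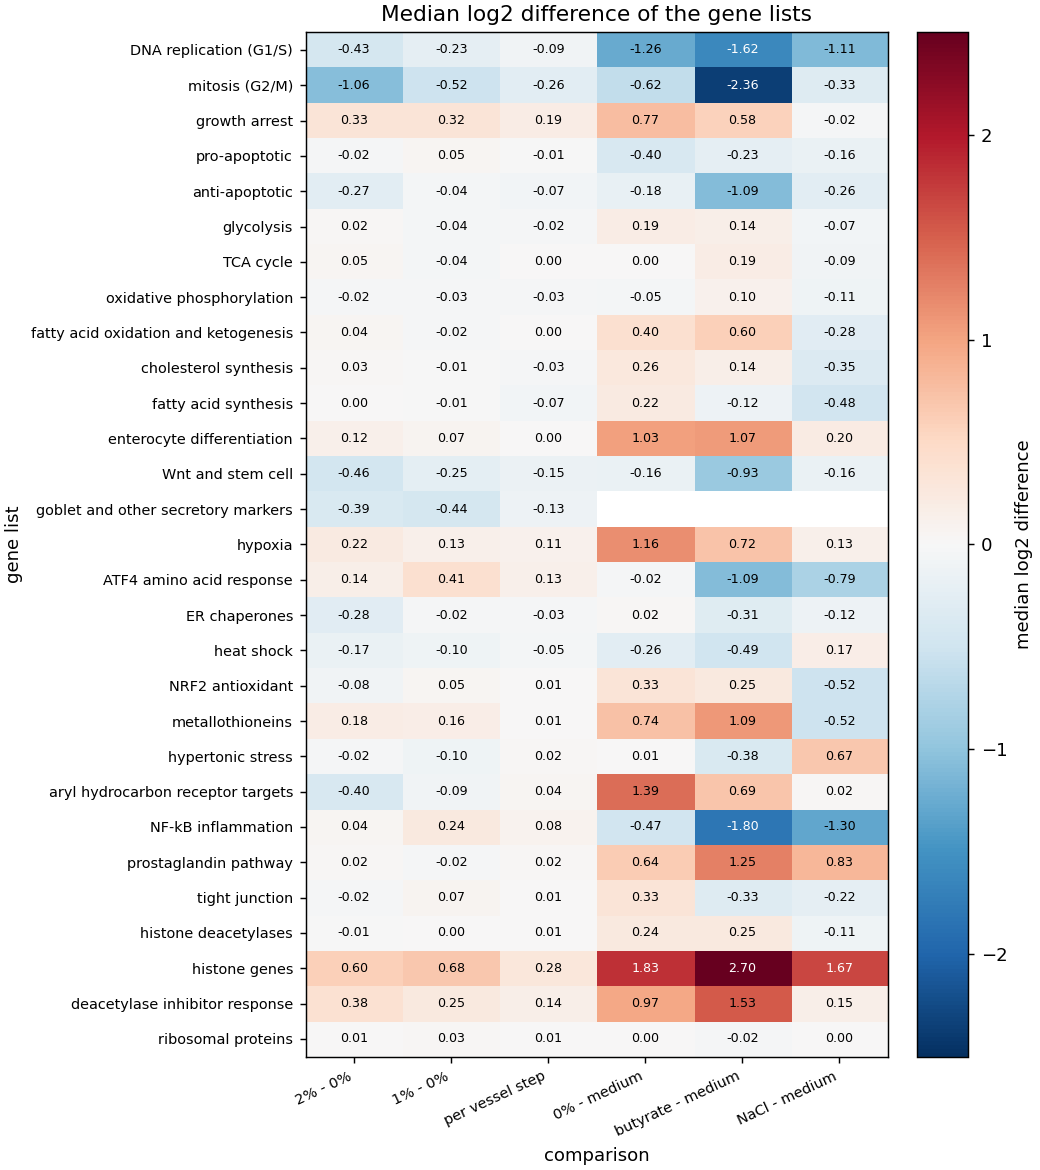
Median log2 difference of each gene list (lines) in 6 comparisons (columns): 2% and 1% against 0% polydextrose, the trend per vessel, and 0% fluid, butyrate and NaCl against medium, with blue for negative and red for positive medians and blank where a list had too few genes. Mitosis genes have a median of -1.06 with 2% polydextrose and -2.36 with butyrate, and histone genes 0.60 and 2.70.

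**Figure D3:**
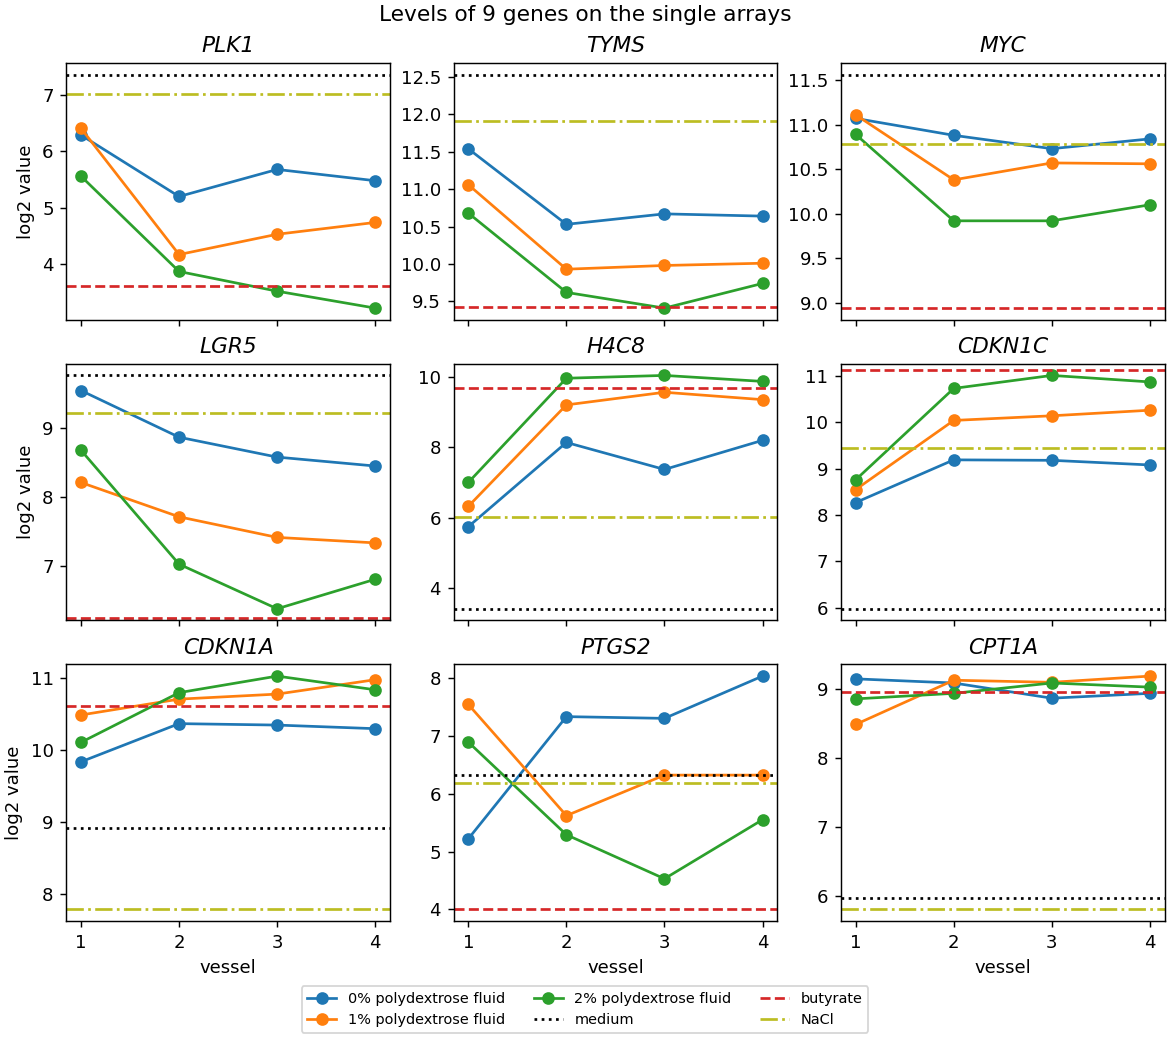
Log2 value of 9 genes (vertical) in vessels 1 to 4 (horizontal), 1 point per array joined by lines for each polydextrose concentration, with horizontal lines for the single medium, NaCl and butyrate arrays. The 2% line of PLK1 lies below its 0% line and that of H4C8 above it in each of the 4 vessels, while for PTGS2 the order in vessel 1 is the opposite of that in vessels 2 to 4.

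The comparison of 1% with 0% polydextrose tests the lower concentration. Mitosis genes fell here too: 11 of 24 fell and 13 did not pass (median -0.52), among them BIRC5, which acts in chromosome segregation (-0.96), KIF20A, a kinesin of cytokinesis (-0.96), and CCNB1, the mitotic cyclin (-0.91). Histone genes rose, 6 of 9 (median 0.68), with H4C8 at 1.25, and CDKN1A rose by 0.52 among the 3 of 12 growth arrest genes that rose. Of 12 Wnt and stem cell genes 3 fell, with LGR5 at -1.20. Among the genes that passed with a log2 value of 5 or more in all 8 arrays, the stress transcription factor ATF3 (1.37), H4C8, FOS (1.20) and the epithelial protein SPRR1A (1.20) had the largest rises and LGR5 and DOCK8 (-1.10) the largest falls. The Notch target HEY1 rose by 1.33, with 1 array of each concentration under log2 5, and BCL2L15, of the BCL2 family (-1.22), and the DNA repair nuclease GEN1 (-1.04) fell, with 3 arrays and 1 array of 1% under it. MYC (-0.23, adjusted p = 0.261) and PTGS2 (-0.52, adjusted p = 0.671) did not pass. In the limma fit without vessel 1, chosen after seeing the data, both passed, MYC at -0.32 (adjusted p = 0.0472) and PTGS2 at -1.47 (adjusted p = 0.0132). The 3′ to 5′ difference of ACTB was lower with 1% than with 0% in vessels 2 to 4 and higher in vessel 1. It was not in the model.

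In all, 418 genes passed by limma, 230 up and 188 down, each with 1 sign in all 4 vessels, and 16 of them changed at least 2-fold. By camera 8 of 29 lists passed. Mitosis (adjusted p = 2.42e-15) had an adjusted p = 0.439 with an estimated correlation, DNA replication (1.76e-06, 3 of 27 fell) and metallothioneins (0.0103, 0 passed by limma) an adjusted p = 0.491 with an estimated correlation, and histone (2.95e-05), growth arrest (0.00109) and inhibitor response genes (0.00212, 2 of 10 rose) an adjusted p = 0.122 with an estimated correlation. The ATF4 list (0.000143, 1 of 14 rose) had an adjusted p = 0.747 and the Wnt list (0.000777) an adjusted p = 0.594 with an estimated correlation. Adjusted over the list alone, 22 mitosis, 12 DNA replication, 4 Wnt and 1 histone gene fell, and 7 histone, 8 growth arrest, 7 ATF4, 3 inhibitor response and 3 metallothionein genes rose. Without vessel 2 of 1% the metallothioneins no longer passed (0.052).

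With no block for vessel the gene count at 1% was 0 by limma (1125 at an unadjusted p under 0.05), and the growth arrest (0.0598) and histone lists (0.0509) no longer passed. The count was 1136 without vessel 1 (1332 with no block as well), 1 from the 8 arrays of these concentrations alone and 258 with no filter for low signal. Left out in turn, vessels 1 to 4 of 0% gave 1185, 9, 21 and 45 genes, vessels 1 to 4 of 1% gave 43, 137, 22 and 0 (1624 at an unadjusted p under 0.05), and vessels 2 and 4 of 2% gave 146 and 143. All 17 genes that passed and were picked for this comparison by the rule for named genes, not all of them named here, thus lost their call without vessel 4 of 1%.

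Between 2% and 1% polydextrose 0 genes passed by limma, although 1608 of 8737 had an unadjusted p under 0.05 against 437 by chance. The smallest adjusted p was 0.0739, for GATM, an enzyme of creatine synthesis (0.55), and for RCCD1 (-0.78). The DNA repair partner BARD1 (-0.49, adjusted p = 0.107) and the condensin subunit NCAPH (-0.78, adjusted p = 0.113) came next, the last with values partly under log2 5. As a group the mitosis genes were lower at 2% than at 1% by camera (median -0.52, adjusted p = 3.83e-14), with an adjusted p = 0.531 with an estimated correlation, and all 24 fell when adjusted over the list alone. DNA replication genes also passed by camera (median -0.19, adjusted p = 2.04e-05), with an adjusted p = 0.732 with an estimated correlation, and 8 fell adjusted over the list alone. Of the other lists, receptor targets (-0.24, 0.00534) and histone genes (0.24, 0.0137) had an adjusted p = 0.531 with an estimated correlation, NRF2 genes (-0.18, 0.00613) one of 0.774, and ATF4 genes (-0.25) and endoplasmic reticulum chaperones (-0.18, both 0.0161) one of 0.801. With no block for vessel the count stayed at 0 (697 at an unadjusted p under 0.05), and the histone list no longer passed (0.325). The histone list also lost its call without vessel 3 of 2% (0.051), NRF2 genes without vessel 1 of 2% (0.0756), chaperones without vessel 1 of 1% or vessel 4 of 2% (up to 0.291) and ATF4 genes without either of these or vessel 1 of 2% (up to 0.451). Without all arrays of vessel 1 ATF4 (0.0955) and NRF2 genes (0.0742) lost theirs, and with the mean of all probe sets the chaperones did (0.0552). Without vessel 1 of 0% 579 genes passed, and without all arrays of vessel 1 141.

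The butyrate array was compared with the medium array to give the effect of a known fermentation product. There was 1 array on each side, so genes were counted from a 2-fold difference without a test. Only an alternative, given further below, used a spread borrowed from the fermentation arrays. Division genes were lower with butyrate: 23 of 24 mitosis genes were lower (median -2.36, or -2.31 with 3 low genes at their bound), with the cyclin CCNA2 at -3.30 and PLK1, under log2 5 with butyrate, at -2.36 or below, and 21 of 27 DNA replication genes were lower (median -1.62), with TYMS at -3.10 and MCM5 at -2.94. Of 9 histone genes 7 were higher (median 2.70), with H4C8 and H2BC21 under log2 5 in medium and higher by at least 4.70 and 4.67, and of 10 genes of the response to deacetylase inhibitors 8 were higher (median 1.53), including the protease inhibitor SERPINI1 (at least 3.23), the actin-severing GSN (2.78), the chaperone CLU (2.19) and CDKN1A (1.70). CDKN1C was higher by 5.14 and GADD45B by 2.25 among 4 of 11 growth arrest genes, of which 1 was lower. Among the 7584 genes at log2 5 or more on both arrays, the largest differences were in KRTAP3-1 (7.54) and, downward, in the chemokine CXCL2 (-5.80). Under log2 5 in medium were AQP3, a water and glycerol channel (higher by at least 7.72), ZCCHC12 (at least 4.89), DHRS2 (at least 4.79) and DNER (at least 4.17), and under it with butyrate were CXCL3 (-6.68 or below), the alarmin IL33 (-4.04 or below) and CRTAM (-3.50 or below). The 3′ to 5′ difference of ACTB was 0.951 in medium, the highest of the 15 arrays, and 0.585 with butyrate.

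Inflammatory and stem cell genes were lower with butyrate too. Of 10 NF-kB genes 6 were lower (median -1.80, or -1.59 with 2 low genes at their bound), among them the chemokines CXCL2 and CXCL1 (-4.97). Of 14 ATF4 genes 8 were lower (median -1.09), with the cystine transporter SLC7A11 at -5.34 and TRIB3 at -3.44. Relative to its mean over the 15 arrays, the NF-kB list was at 0.732 in medium, -1.211 with NaCl and -1.386 with butyrate. The ATF4 list was at -0.172, -1.165 and -1.568, so most of both differences from medium was also seen with NaCl. The Wnt and stem cell list was at 0.625, 0.423 and -0.878. Of 12 Wnt and stem cell genes 5 were lower (LGR5 -3.54, ASCL2 -3.35, MYC -2.62), and of 6 anti-apoptotic genes 4 were lower (CFLAR -3.04, BCL2L1 -2.28). Of 15 genes of fatty acid oxidation 5 were higher (CPT1A 2.99, SLC25A20 2.04, ETFDH 1.88), as were 5 of 6 metallothioneins (median 1.09; MT1F 1.5) and 4 of 10 hypoxia genes, while 1 fatty acid oxidation gene and 1 hypoxia gene, VEGFA (-2.57), were lower. In the prostaglandin pathway PTGS1, the constitutive cyclooxygenase, was higher by at least 1.92 and the phospholipase PLA2G4A by at least 1.93, both from under log2 5 in medium, while PTGS2 was under it with butyrate (-1.33 or below). PCNA differed by -1.05 and CCND1 by -0.26. The 16 ribosomal protein genes had a median of -0.02 and 0 of them passed 2-fold.

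In all, 2511 of 8057 genes bright enough to compare (31.2%) differed at least 2-fold, 1258 higher and 1253 lower, while 18 pairs of fermentation arrays of the same concentration gave 5 to 571 such genes (median 81). Against 10000 random lists of genes of like level, the mitosis, DNA replication, NF-kB and ATF4 medians lay at percentile 0 and the histone and inhibitor response medians at percentile 100. Of the 2511 genes 473 lay under log2 5 on one array, and all 2511 still counted at their bound, as the limits of log2 6 and 5 ensure. With the mean of all probe sets of a gene the count was 1643, and with a higher limit for signal 1552.

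The NaCl array was compared with the medium array to show what added salt does. The betaine transporter SLC6A12, which takes up a compatible solute under osmotic stress, was at 7.65 and in medium under log2 5, a difference of at least 2.65, and the inositol transporter SLC5A3 was higher by 3.53. They were the 2 higher genes among 8 of the hypertonic stress list (median 0.67, percentile 99.74), of which 1 was lower. Among the 7681 genes at log2 5 or more on both arrays the largest difference was in the chemokine CCL26 (13.01 against 5.56). The protease-like PRSS35 (at least 5.59), the placental alkaline phosphatase ALPP (at least 4.57) and the protease inhibitor CST1 (at least 4.22) were under log2 5 in medium. Of 27 DNA replication genes 15 were lower (median -1.11, percentile 0), with RRM2, a ribonucleotide reductase subunit, and CDC6, which loads the replicative helicase, both at -1.78, but 5 of 24 mitosis genes were (median -0.33). Of 11 NF-kB genes 6 were lower and 2 higher (median -1.30, percentile 0): CXCL2 was at -4.34, CXCL8 at -3.40 and CXCL3 at -3.32, while CCL2 was higher by at least 3.70. Of 8 histone genes 5 were higher (H2BC21 by at least 2.19, H4C8 by at least 1.01). The cyclooxygenase PTGS1 (at least 1.37) and the prostaglandin E synthase PTGES (2.78) were higher, PTGS2 differed by -0.15, and CDKN1A was lower by 1.13 while CDKN1C was higher by 3.47. Of 14 ATF4 genes 6 were lower, with SLC7A11 at -2.49 and DDIT3 at -2.44. MYC (-0.78), CCND1 (-0.77), PCNA (-0.54) and CPT1A (-0.17) differed less than 2-fold. The 3′ to 5′ difference of ACTB was 0.641 with NaCl, against 0.951 in medium. There were 1307 of 7874 genes (16.6%) past 2-fold, 703 higher and 604 lower, 806 with the mean of all probe sets and 688 with a higher limit for signal.

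The fluid fermented without polydextrose was compared with medium to show the background of the fermentation itself, as the mean of the 4 arrays with 0% against the single medium array. Of 27 DNA replication genes 18 were lower (median -1.26), with MCM5 at -2.77, MCM4 at -1.80 and TYMS at -1.68, and 6 of 24 mitosis genes were lower (median -0.62), with PLK1 at -1.69. Of 8 histone genes 5 were higher (H4C8 by at least 2.36, H2BC21 by at least 2.18) and of 11 growth arrest genes 5 were (CDKN1C 2.94, CDKN2B 2.26, CDKN1A 1.30). Of 10 hypoxia genes 6 were higher (median 1.16), among them NDRG1 (2.58), ANKRD37 (2.45) and the oxygen sensor EGLN3 (1.5). List means were also taken relative to the mean over all arrays. DNA replication was at 1.359 in medium, 0.24 with NaCl and -0.034 to 0.57 with 0% fluid. Most of this difference was thus also seen with NaCl. In the same order mitosis was at 1.224, 0.75 and 0.281 to 0.941, and histone genes at -1.975, -0.531 and -0.98 to -0.015. Growth arrest (-1.07, -0.868 and -0.447 to 0.17) and hypoxia (-1.117, -0.945 and -0.65 to 0.565) lay near medium with NaCl. Among the 7600 genes at log2 5 or more on all 5 arrays the largest differences were in the lectin LGALS1 (5.09) and, downward, in the collagen chaperone SERPINH1 and in CXCL3 (both -2.90). AQP3 (at least 5.94), RNF128 (at least 2.77), the sterol exporter ABCG1 (at least 2.35) and the collagen chain COL1A1 (at least 1.65) were under log2 5 in medium. APOL6 was under it with 0% fluid (-2.37 or below), as were 3 of the 4 arrays for CRTAM (-4.76) and for CDC25A, a phosphatase of cell cycle entry (-3.26). The 3′ to 5′ difference of ACTB was 0.951 in medium and 0.582 to 0.726 with 0% fluid. CPT1A was higher by 3.04, HMOX1 by 2.36, and PTGS2 (0.64), MYC (-0.68), PCNA (-0.98) and CCND1 (-0.16) differed less than 2-fold. None of 7 hypertonic stress genes passed 2-fold (median 0.01, percentile 42.53).

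In all, 986 of 7820 genes (12.6%) passed 2-fold, 611 higher and 375 lower, 638 with the mean of all probe sets and 492 with a higher limit for signal. Against the NaCl array there were 1672, of which 505 were shared, and ABCG1 (-0.43), H2BC21 (-0.01), CDKN1C (-0.52), EGLN3 (-0.21) and CXCL3 (0.42, against -2.90 from medium) then had the other sign. Among 7747 genes compared in both, 502 of 578 genes higher with 0% fluid were also higher with butyrate and 351 of 375 lower genes were also lower, against 76.6 and 60.7 if the sets were independent. The medium array is part of both differences. Noise drawn for each gene on its own with the residual SD of the fermentation fit, with that shared control, gave 4.7 and 5.1 genes. Its covariance was 0.034 against 0.727 in the data, and its r was 0.632 against 0.836. Such noise holds no differences between vessels and no shift common to many genes, so its counts may be too low. Part of the excess may come from the shared control, which a single medium array cannot split. For NaCl and butyrate the overlaps were 232 of 524 higher and 241 of 628 lower genes, against 69.5 and 101.6 if independent and 6.6 and 7.0 from noise, with a covariance of 0.288 against 0.035. Their r of 0.323 lay under the 0.502 that noise with a shared control gave.

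The change from 0% to 2% polydextrose was then set against the butyrate difference, gene by gene. Of the 1820 genes that passed, 1782 (97.9%) differed in the same direction with butyrate, including DNER, DHRS2, ZCCHC12, H4C8 and CDKN1C upward and PLK1, TYMS, LGR5 and ALDH3A1 downward. Of those that also passed 2-fold with butyrate the signs were shared by 1258 of 1260. CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, was an exception: it was at 6.60 with butyrate and 4.95 in medium, but with NaCl as the control for butyrate it differed by -0.91, and it fell by 0.88 at 2% (adjusted p = 0.0139, up to 0.0569 without vessel 2 or 3 of 0%). Across 8737 genes, which are not independent replicates, Pearson's r was 0.805 and Spearman's rho 0.782. Of the 35 splits of the 8 arrays 5 gave an r as large (permutation p = 0.143, highest other r 0.822), a planned count in which most splits mix the vessels. Of the 8 splits that part all 4 vessel pairs, a count added after the data were seen, only the real one gave an r as large (highest other 0.731), but 8 are too few for a share under 0.05. With butyrate against NaCl r was 0.644 (5 of 35 splits as large, highest other 0.664, and 1 of the 8, highest other 0.586), and with the NaCl effect it was 0.238. Within vessels the effect of 2% had an r of 0.370 in vessel 1 and of 0.738, 0.679 and 0.771 in vessels 2 to 4. For the effect of 1% r was 0.611, 12 of 35 splits and 2 of the 8 gave one as large, and within vessels it was -0.031 in vessel 1 and 0.639, 0.536 and 0.687 in vessels 2 to 4.

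The distance of each array to the butyrate array, as the root mean square log2 difference over genes, was 0.744 ± 0.063 with 0% fluid, 0.670 ± 0.163 with 1% and 0.549 ± 0.141 with 2% (SD, n = 4). The distance with 2% was shorter than with 0% in 4 of 4 vessels, with an exact two-sided permutation p of 0.0857 (0.152 adjusted over 4 comparisons). Paired by vessel the exact p was 0.125, the smallest that 4 pairs allow. The distance with 1% was shorter in 3 of 4 vessels (exact p = 0.457). To the medium array the distance was 0.784 ± 0.085 with 0%, 0.940 ± 0.117 with 1% and 1.014 ± 0.147 with 2% (exact p = 0.114 for each concentration against 0%, 0.152 adjusted). It was longer than with 0% in 4 of 4 vessels at each concentration (exact p paired by vessel 0.125). None of these 4 comparisons passed.

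**Figure D4:**
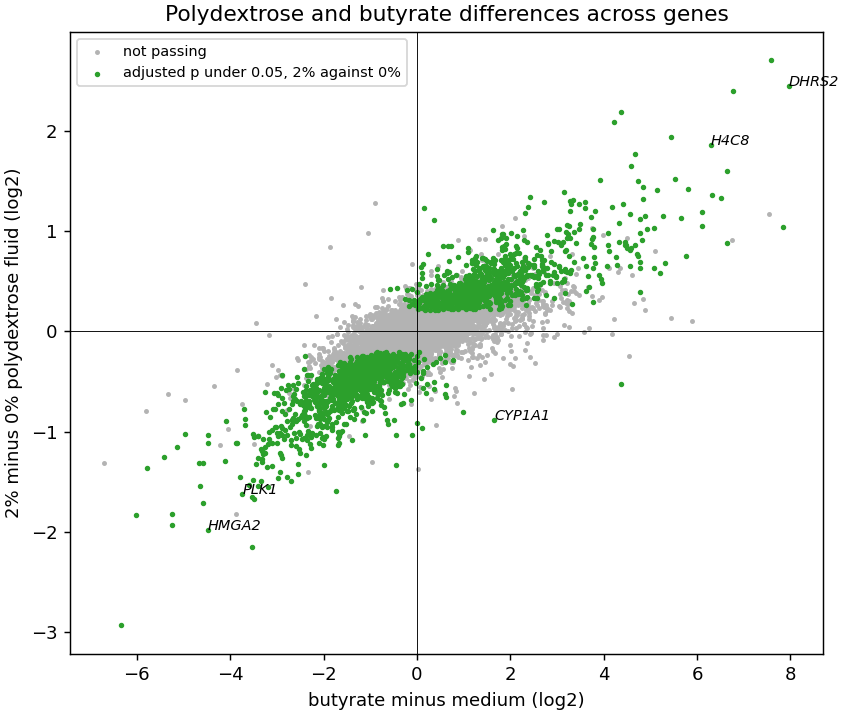
Log2 change from 0% to 2% polydextrose (vertical) against the log2 difference of butyrate from medium (horizontal), 1 point per gene for 8737 genes, with green for the genes that passed between 2% and 0% and a few genes labelled. The points have r 0.805, with DHRS2 and H4C8 at the upper right and PLK1 and HMGA2 at the lower left.

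The 4 vessels were compared to ask how the fluid's effect changes along the simulated colon. In a trend over vessels 2 to 4 alone, chosen after seeing the data, 0 genes passed by limma. The slopes per vessel below thus cannot be read as a steady gradient. From vessel 1 towards vessel 4, 4 of 12 growth arrest genes rose, with the growth arrest gene GADD45A at 0.25 per vessel, BTG1 at 0.20 and the kinase inhibitor CDKN2B at 0.20, and of 14 ATF4 genes 2 rose, including the asparagine synthetase ASNS (0.26). Histone genes rose in 2 of 9, H1-2 (0.29) and H2AC6 (0.28). Among the 311 genes that passed with a log2 value of 5 or more in all 12 arrays, the largest rises were in the transcription factor ATF3 (0.56), ADPRM (0.53) and DUSP1, a phosphatase that ends kinase signals (0.49). The largest falls among them were in SRM, the spermidine synthase (-0.44), and LGR5 (-0.43), and TACC3, a spindle protein, fell by 0.35. ULBP1, a stress ligand seen by natural killer cells, rose by 0.68 with 7 of the 12 arrays under log2 5, and BCL2L15 (-0.43) fell with 6 under it. Of 24 mitosis genes 0 passed by limma over all genes, and 19 fell when adjusted over the list alone. MYC (-0.16, adjusted p = 0.135) and PTGS2 (0.02, adjusted p = 0.959) did not pass. At each concentration the 3′ to 5′ difference of ACTB was highest in vessel 1.

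By limma 344 genes passed along the vessels, 147 up and 197 down. By camera 9 of 29 lists passed: mitosis (median -0.26, 9.66e-07), growth arrest (0.19, 3.2e-05), ATF4 (0.13, 3.33e-05), Wnt (-0.15, 0.000888), histone (0.28, 0.000888), DNA replication (-0.09, 0.00177), inhibitor response (0.14, 0.00177), hypoxia (0.11, 0.0246) and oxidative phosphorylation (-0.03, 0.0464). Each had an adjusted p = 0.712 with an estimated correlation. Without vessel 1 of 0% the DNA replication (0.236) and hypoxia lists no longer passed, hypoxia did not without vessel 4 of 0% either (up to 0.412), and oxidative phosphorylation lost its call in 7 of the 12 fits without 1 array: vessels 1, 2 and 4 of 0%, vessel 2 of 1% and vessels 2, 3 and 4 of 2% (up to 0.416). Adjusted over the list alone, 9 growth arrest, 7 ATF4, 6 histone and 3 inhibitor response genes rose. By the same adjustment 8 Wnt, 5 DNA replication, 3 oxidative phosphorylation and 1 histone gene fell. Vessel 1 stood apart: 3035 genes passed for vessels 2 to 4 against vessel 1, a comparison chosen after seeing the data, 2021 for vessel 4 against vessel 1, and 0 along vessels 2 to 4 (915 at an unadjusted p under 0.05). Left out in turn, vessels 1, 3 and 4 of 0%, vessels 1 and 3 of 1% and vessel 1 of 2% gave 0 genes (1714 to 2650 at an unadjusted p under 0.05), vessels 3 and 4 of 2% gave 1 and 4, vessel 4 of 1% gave 2, and vessel 2 of 1% and of 2% gave 677 and 883. All 29 genes that passed and were picked for this comparison by the rule for named genes, not all of them named here, thus lost their call in some of these fits.

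Whether the polydextrose effect grew or shrank along the vessels was tested as an interaction, in log2 per 1% of polydextrose and vessel. No gene passed by limma (949 of 8737 at an unadjusted p under 0.05), and the smallest adjusted p was 0.202, for STON2, an endocytic adaptor (0.30, with 7 of 12 arrays under log2 5), and WRAP53 (0.21). Genes of hypoxia (median -0.22, adjusted p = 1.87e-07 by camera) and glycolysis (-0.09, 1.8e-05) each had an adjusted p = 0.795 with an estimated correlation. With the preset correlation they kept their call in each fit without 1 array. KDM3A, a histone demethylase induced by low oxygen, was at -0.22, P4HA1, a collagen hydroxylase, at -0.26, the glycolytic aldolase ALDOC at -0.39 and the glucose transporter SLC2A1 at -0.21, each with an adjusted p of 0.421. Adjusted over the list alone, 7 of 11 hypoxia genes had a negative interaction that passed. Endoplasmic reticulum chaperones (-0.11, 1.8e-05), mitosis (-0.07, 7.39e-05), DNA replication (0.04, 0.000124), ATF4 (-0.08, 0.00211), NF-kB (-0.08, 0.0142) and goblet cell genes (-0.10, 0.0263) passed as well, each with an adjusted p = 0.795 with an estimated correlation. With no filter for low signal goblet cell genes did not (-0.02, 0.693). Without vessel 1 of 0% these 6 lost the call (0.175 to 0.999), as did all but DNA replication without 1 more array: mitosis without vessel 1 of 2%, chaperones, ATF4 and NF-kB genes without vessel 4 of 0%, and goblet cell genes without either of these or vessel 4 of 2%.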

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

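The counts of other splits for the 5 gene counts, the correlation with the butyrate effect, the linear interaction and the search for outlying arrays were planned, and the other tests in this part were chosen after the results were seen.

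In 15 of 52 groups of 4 arrays 1 array lay far from the other 3, where chance gives about 1 in 20 groups (2.6 here), and in each it was the array of vessel 1. Among the genes, CDKN1A in vessel 1 of 0% was at 9.844 (others 10.299 to 10.367), PCNA there at 11.850 (11.353 to 11.419), H4C8 in vessel 1 of 1% at 6.318 (9.213 to 9.567) and of 2% at 7.004 (9.883 to 10.046), and CPT1A in vessel 1 of 1% at 8.478 (9.094 to 9.177). The 3′ to 5′ difference of ACTB in vessel 1 of 2% was 0.620 (0.547 to 0.551) and that of GAPDH in vessel 1 of 1% was 0.042 (-0.080 to -0.064). The array of vessel 1 of 1% was 0.913 from butyrate (0.559 to 0.611), 0.765 from medium (0.994 to 1.002) and 0.889 from NaCl (1.038 to 1.051), and that of 0% was 0.658 from medium (0.822 to 0.835). On principal component 1 vessel 1 was at -19.75 with 0%, -17.79 with 1% and -6.19 with 2%, and on component 2 vessel 1 of 1% was at 20.85 (2.15 to 3.41). These groups share arrays and genes, so they are not independent of each other.

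The effect of polydextrose differed between vessel 1 and vessels 2 to 4 in 102 genes by a limma test of the difference itself, a form of the interaction chosen after seeing the data, with 30 differences positive and 72 negative. CDKN1C changed by 0.49 from 0% to 2% in vessel 1 and by 1.72 in vessels 2 to 4 (adjusted p of the difference 0.0307), DHRS2 by 0.33 and 3.15 (0.0369), with its 4 arrays of 0% under log2 5, and CADPS by 1.05 and -2.78, with its arrays of 2% in vessels 2 to 4 under it. PTGS2, CXCL1, CXCL3 and H4C8 were not among the 102. The planned linear interaction passed for 0 genes by limma, with 949 at an unadjusted p under 0.05.

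The first pattern weighed is that vessel 1 differed from vessels 2 to 4, with 3035 genes passing, 1348 higher and 1687 lower in vessels 2 to 4: all 24 mitosis genes were lower there (median -0.95), 11 of 12 Wnt and stem cell genes too (-0.53), and 9 of 12 growth arrest genes were higher (0.50). A single odd array, vessel 1 of 1%, is argued against as the whole cause, though narrowly by gene count. In the fit without it 1656 genes passed, and vessel 1 of 0% and of 2% lay apart on component 1 as well. Of the 3035 genes 51.2% still passed (median size 0.403 against 0.442), just over a bound set after the results were seen. That 100% kept their sign says little, since they were picked with the other arrays of vessel 1 among the data. RNA quality cannot be told apart from the vessel, because the ACTB difference was highest in vessel 1 at each concentration: with it in the model 13.4% of the genes still passed, while their median size went from 0.442 to 0.383, so the calls ended with a smaller loss of size than of number. With the GAPDH difference instead 1952 passed. A difference in the fluid of the ascending colon vessel, such as a lower content of fermentation acids, may be a cause and stays open as a hypothesis, since no metabolite values were available.

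The second pattern is that fluid without polydextrose already differed from medium in the direction of butyrate, with 502 of 578 higher and 351 of 375 lower genes shared. A medium array that was itself off is argued against as the whole cause, though only weakly. The differences 0% minus NaCl and butyrate minus medium, which share no array, correlated across genes at 0.41. This r has no spread or no-change value, and other splits of fermentation arrays reached 0.822 with the butyrate difference. Medium also had the highest ACTB difference of the 15 arrays (0.951), and its RNA quality was not tested. For the higher genes, salt in the fluid is argued against as the whole cause, though only weakly. The genes higher with 0% fluid had a median NaCl difference of 0.401, under the bound of 0.5 that was set after the results were seen. The bootstrap (0.264 to 0.499) resampled genes from 1 NaCl and 1 medium array. It thus does not measure the spread between arrays, and its upper end lay under the bound by little. Of the 611 genes 31.3% were past 2-fold with NaCl and 83.3% with butyrate. The lower genes were not tested for salt, so it stays open for them. DNA replication genes had medians of -1.26 with 0% fluid and -1.11 with NaCl. In the same order NF-kB genes had -0.47 and -1.30, and mitosis genes -0.62 and -0.33. Butyrate made in the simulator without polydextrose may account for part of this, a hypothesis that these data did not test directly.

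The third pattern is that the effect of 2% polydextrose lay along the butyrate effect, with r 0.805. Other splits of the same arrays do so as well: the slope on the butyrate effect, tried after r, was 0.232, and 4 of 35 splits were as steep (highest other 0.262), but most of these splits mix the vessels. Among the 8 that part all 4 vessel pairs only the real one was as steep (highest other 0.182) or had an r as large (highest other 0.731), but 8 splits are too few for a share under 0.05, so an axis shared by such splits stays open. Salt as the whole cause was weighed by the 1206 tested genes past 2-fold with NaCl. At 2% they changed in the NaCl direction by a median of 0.129 (0.106 to 0.152 over the vessels). This lay under the 0.482 of the 1782 genes of the pattern, but those were picked for their change, so the comparison cannot decide. The 638 of the 1206 genes that were under 2-fold with butyrate changed by 0.028, so these hardly moved at 2%. The salt-induced SLC5A3 differed by 0.11 (SE 0.141) at 2% and 3.53 with NaCl. Mitosis genes had medians of -1.06 at 2% and -0.33 with NaCl, but DNA replication genes had -0.43 and -1.11. Of the pattern genes 66.2% had the NaCl sign, with a median NaCl difference of 0.275 in the direction of the 2% change. More butyrate in the fluid from polydextrose may explain the shared direction. It remains a hypothesis, since the splits were too few to set the real one apart. RNA quality was not tested for this pattern and stays open too. The ACTB difference was 0.951 in medium and 0.585 with butyrate, and lower with 2% than with 0% in each vessel. With 1% it was higher than with 0% in vessel 1 (0.924 against 0.726), where r was -0.031. In vessels 2 to 4 it was lower with 1% and r was 0.536 to 0.687. At 2%, however, it went from 0.726 to 0.620 in vessel 1 (r 0.370) and from 0.582 to 0.551 in vessel 4 (r 0.771).

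Other splits of the arrays were counted for each gene count. For 2% against 0% the real split gave 1820 genes, 1 of 35 as large, and the highest other 326, and for 1% against 0% it gave 418, 1 of 35 as large (highest other 7). With vessel as a block only the 8 splits that part all 4 vessel pairs compare with the real one, and 8 are too few for a share under 0.05, which the planned count over 35 splits had not allowed for. In both comparisons the highest other was 1 of these 8. Along the vessels the real order gave 344, 1 of 100 orders drawn within each concentration as large (highest other 1). Those planned orders took apart the vessels that the concentrations share, and the 12 orders that keep them (highest other 0) are too few for a share under 0.05. For 2% against 1% and for the interaction the real count was 0, which every split reaches by construction (35 of 35, highest other 0, and 100 of 100, highest other 2, or 9 among the 12), so these counts say nothing about chance.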

How the results depend on the processing

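The fits without vessel 1, vessels 2 to 4 against vessel 1, the trend over vessels 2 to 4 and the dose trend in vessels 2 to 4 against vessel 1 were chosen after seeing the data. Of the genes that passed for 2% against 0%, 37 of 65 picked for naming kept their call in each fit without 1 array, as did 6 of 8 lists. At 1% 0 of 17 genes and 7 of 8 lists did, and along the vessels 0 of 29 genes and 6 of 9 lists. The counts at 2% and 1% stayed within 1.5 times under quantile normalization, centring and a robust prior. The deposited values were already normalized, with array medians of 2.663 to 2.709, so normalization again or centring had little left to change. Genes near background, such as ALPI, could not be compared. Array weights did not fully converge in 4 fits. The lone arrays of medium, NaCl and butyrate were assumed to vary like the fermentation arrays where a spread was borrowed. The cause was not tested for the values below, except where fewer genes, arrays or a stricter limit were used.

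For 2% against 0% the count (1820) was 3957 with array weights, 0 with no block, 863 from 8 arrays, 633 with 1.5-fold, 3205 without vessel 1 (3352 with no block) and 656 to 3058 without 1 array. For 1% against 0% (418) it was 258 with no filter, 1700 with weights, 0 with no block, 1 from 8 arrays, 134 with 1.5-fold, 1136 without vessel 1 (1332 with no block) and 0 to 1185 without 1 array. For 2% against 1% (0) it was 755 with weights, 61 from 8 arrays, 141 without vessel 1 (241 with no block) and 0 to 579 without 1 array. Along the vessels (344) it was 1 with no filter, 560 with a filter at log2 7, 163 with mean probe sets, 0 for single probe sets, 650 with a robust prior, 1 with weights, 2021 for vessel 4 against vessel 1, 1370 by F-test, 0 without concentration in the model, 3035 for vessels 2 to 4 against vessel 1, 0 over vessels 2 to 4 and 0 to 883 without 1 array. The limma counts of 0 had 1952, 1125, 4865, 1922 and 915 genes at an unadjusted p under 0.05 (2% and 1% with no block, single probe sets, no concentration, vessels 2 to 4). The interaction (0) gave 102 as a dose trend in vessels 2 to 4 against vessel 1.

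At a limit of log2 8, with mean probe sets and with a borrowed spread, butyrate (2511) gave 1552, 1643 and 4575 genes, NaCl (1307) 688, 806 and 2979, and 0% fluid (986) 492, 638 and 3408. Against NaCl 0% fluid gave 1672. The correlation (0.805) was 0.370 in vessel 1.

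Signs turned as follows. CPT1A at 2% (-0.03, not passing) was 0.207 with mean probe sets, 0.052 without vessel 1 (both fits) and -0.120 to 0.114 without 1 array. Along the vessels PTGS2 (0.02, not passing) was -0.295 for vessels 2 to 4 against vessel 1 and -0.266 to 0.247 without 1 array, and MYC (-0.16, not passing) was 0.054 over vessels 2 to 4. With NaCl as control CYP1A1 was -0.913 for butyrate, and for 0% fluid ABCG1 was -0.431, H2BC21 -0.010, CDKN1C -0.523, EGLN3 -0.208 and CXCL3 0.423. Without 1 array the interaction medians were -0.161 to 0.001 for mitosis, -0.164 to 0.043 for ATF4 and -0.146 to 0.011 for NF-kB genes.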

Other observations

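No tests were added for this part, and no explanation was tried.

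Targets of the aryl hydrocarbon receptor, which senses many ring-shaped compounds including bacterial indoles, were higher with 0% fluid than in medium. CYP1A1 was at 4.95 in medium, 7.51 with NaCl, 6.60 with butyrate and 9.08 ± 0.38 with 0% fluid (SD, n = 4), so it was higher by at least 4.08 with the fluid, counted from the limit of log2 5 for signal, and CYP1B1 (1.69) and TIPARP (1.39) were higher too. With NaCl CYP1A1 was higher by at least 2.51 and CYP1B1 by 1.46, and with butyrate CYP1B1 was higher by 1.19. With 2% polydextrose CYP1A1 was at 8.20 ± 0.20 (SD, n = 4). The list had a median of 1.39 for 0% fluid against medium (3 of 5 genes higher, percentile 100) and 0.02 with NaCl, where 2 of 5 were higher and 2 lower.

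Cytokine, prostaglandin and metal-binding genes differed between the salt, butyrate and fluid arrays. CCL26, a chemokine for eosinophils, was at 13.01 with NaCl, 5.56 in medium and 8.69 ± 0.53 with 0% fluid (SD, n = 4). The cyclooxygenase PTGS1 was under log2 5 in medium and higher by at least 1.92 with butyrate and by at least 1.37 with NaCl, and rose by 0.63 from 0% to 2% polydextrose (adjusted p = 0.0474), a call that was lost in 9 of 12 fits without 1 array (vessels 2 to 4 of 0%, 2 and 3 of 1% and 1 to 4 of 2%, up to 0.146). The enterocyte list had a median of 1.07 with butyrate (2 of 4 genes higher, 1 lower, percentile 98.20) and 1.03 with 0% fluid (2 of 4 higher, percentile 99.54), against 0.20 with NaCl. Metallothioneins had a median of 1.09 with butyrate, 0.74 with 0% fluid and -0.52 with NaCl.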
